A study of Mus musculus with 6 samples.

How the data were processed

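Transcript abundance was measured by RNA-seq in 6 libraries of mouse aortic vascular smooth muscle cells, 3 controls and 3 treated with exosomes for 24 h. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. The submitters' processing notes name HISAT2, RSEM and DESeq and the mouse genome build GRCm39, without versions. The annotation, read length, strand setting and filters are not given in the sources used here. The vehicle given to control cells is not given in the sources used here either.

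The authors deposited 1 table of 17877 genes, each with an Entrez gene ID, a symbol and 3 values per library. The expected counts deposited by the authors are estimated reads per gene and are not whole for 32.3% to 33.1% of values per library. The authors' FPKM values are scaled by transcript length and sequencing depth, and the authors' TPM values are scaled so that every library has the same sum. FPKM and TPM are rounded to 2 decimals in the deposited table. Each column was matched to a sample by the group and number in its name, and no column of per-sample values was left over. Counts that genes share with near-identical copies were divided by estimation before deposit, so paralogs and pseudogenes carry an error that the counts do not show.

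Total counts lay between 20465762 and 20877411 per library. Every pair of replicates differed by more than sampling noise over 11764 genes with a mean of at least 20 counts, so each library was kept as 1 replicate. Groups were taken from the sample titles. The choices of test, named genes, gene lists and alternative settings, except those said below to have been added, were made before the data were examined.

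Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its default settings (minimum count 10, minimum total count 15), which left 12445 genes and removed 5432, including 748 with 0 counts in all libraries. Libraries were scaled by TMM, the model held the group alone, and the quasi-likelihood F test was adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Normalised read counts are CPM after TMM scaling, given as mean ± SD over 3 replicates. A fold change is the exosome group over the control group. The 1 gene named in the study's title was also tested by an exact two-sided permutation test of its 6 CPM values.

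The 30 gene lists, fixed in advance, were tested with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 30 lists, then with an estimated correlation and with fry. Members were counted over all genes and adjusted over the list alone. Named genes were Serpine1, and among called genes with separated groups and a mean of at least 50 counts in the higher group the 8 largest changes and the 4 smallest p-values per direction, leaving out unnamed models and pseudogenes. Up to 4 members with the smallest p were named per list with called members, and 2 members per other list. Further members named in the text to show the range of a list, those that did not pass the test among them, were chosen after their values were seen.

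Seed matches of miR-148a-3p (bases 2 to 8, 7 bases, or 8 with a terminal A) were searched in the longest annotated 3′ UTR per gene of GENCODE M21 transcripts on GRCm38, joined by Entrez ID. Of the table's IDs 17201 matched an Entrez ID there and 16944 had a 3′ UTR. The same search was run with 100 shuffled seeds of the same base composition and, added after these were seen, with all 629 other orders of the seed's bases, of which those with 0.5 to 2 times as many genes were kept, and the difference was given a bootstrap interval over genes (10000 resamples), also added. Because the reference annotation is GRCm38 and the counts were made on GRCm39, UTR coordinates are given for GRCm38 alone. Transcript lengths were derived from the authors' counts and FPKM for 13293 genes with a summed FPKM of at least 0.5, and GC content from GENCODE M21 transcripts, and 98.9% of called genes had both.

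Alternatives were edgeR's RLE factors, library totals, no filter, a mean of at least 50 counts, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, each library left out, a 2-fold minimum and an adjusted p under 0.01. Offsets per library for length and GC content, fitted as smooth trends with mgcv 1.9.3, and limma on log2(TPM + 1) and log2(TPM + 0.1) were added after the data were seen, as were the seed-site test and the median of the cell cycle genes under the other settings. A smaller pseudocount applied to TPM alone.

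The test was tried on simulated counts for the 12445 genes with the real means and library sizes. It recovered 60% of genes changed 1.25-fold, 88% at 1.5-fold, 92% at 2-fold and 100% at 3-fold, 50 genes at each size, with 13 false calls. With a simulated length trend and no true change it made 3363 false calls without offsets and 0 with offsets, the latter over 12145 genes. The simulated trend was smooth, the same in all treated libraries and of a preset size that was not fitted to the real one. These numbers therefore do not estimate how many real calls came from transcript length. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.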

Results

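RNA-seq libraries were compared from mouse vascular smooth muscle cells, the contractile cells of the artery wall, taken from the aortic media of C57BL/6 mice and grown in serum-containing medium. The titles call 3 libraries controls and the design text calls their cells untreated, although the treatment protocol in the labels names exosomes for all 6 samples; the titles were followed. The other 3 came from cells treated for 24 h with exosomes, small secreted vesicles that carry RNA and protein, which had been collected by ultracentrifugation from umbilical cord mesenchymal stem cells. The table held expected read counts for 17877 genes in these 6 libraries. The total count per library lay between 20465762 and 20877411, and between 15137 and 15251 genes had at least 1 count. One count corresponded to 0.0479 to 0.0489 CPM, the read count scaled to library depth. The 10 genes with the most reads took 4.53% to 4.8% of each library, and the translation factor gene Eef1a1 led in all 6. The 2 groups lay at opposite ends of the first principal component, which held 48.1% of the variance. The biological coefficient of variation between replicates was 4.02%. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values below measure only the spread between these samples, which may be technical.

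The comparison asked how 1 day of exosome exposure altered the smooth muscle transcriptome, with miR-148a-3p as the exosomal cargo and Serpine1 as the target named by the study. Serpine1 (Entrez gene 18787) encodes plasminogen activator inhibitor 1, the main inhibitor of tissue and urokinase plasminogen activators. Its normalised read count was 207 ± 6.65 CPM in control cells and 93.5 ± 2.73 CPM in exosome-treated cells (SD, n = 3 each), 2.22-fold lower after treatment. The log2 fold change was -1.15 with a standard error of 0.042 (adjusted p = 2.03e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The expected counts were 4091, 4240 and 4352 in the controls against 1997, 2009 and 1875 after treatment. An exact two-sided permutation test of the 6 values gave p = 0.1, which is the smallest p that 3 against 3 samples allow. Serpine1 was 1 of 17 genes that fell at least 2-fold.

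**Figure D1:**
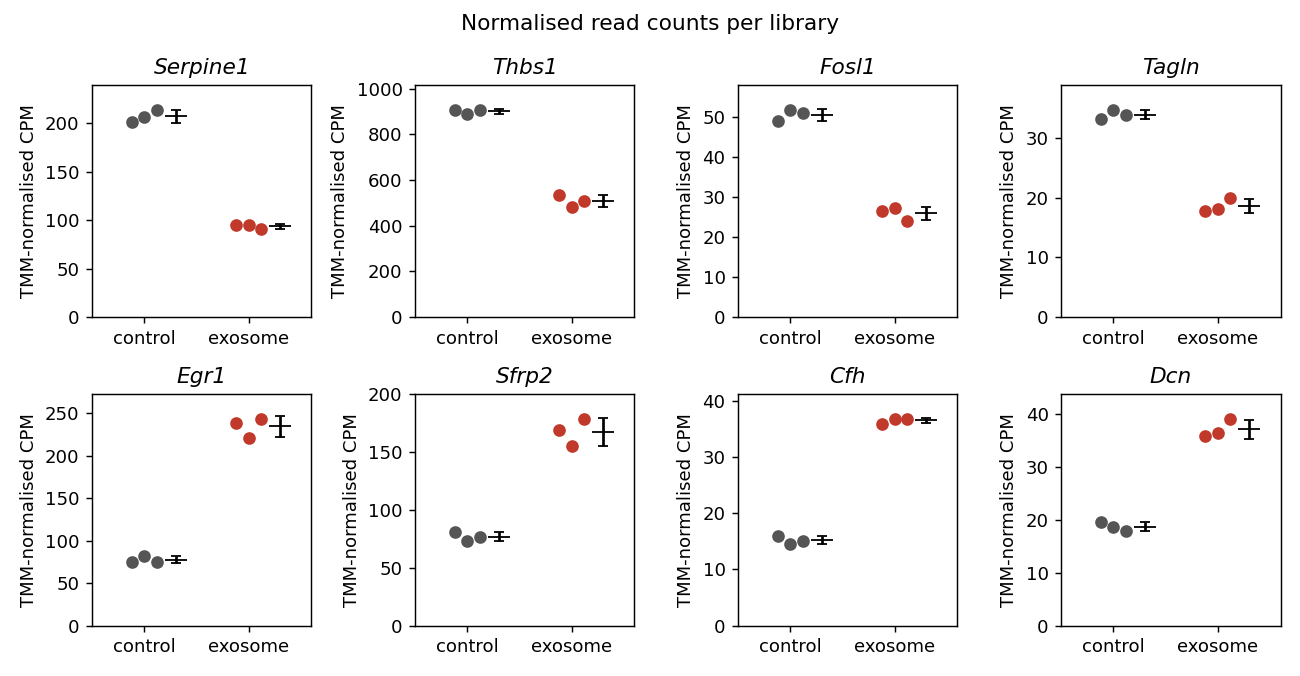
Each panel plots the TMM-normalised read count of 1 gene in CPM (vertical axis, starting at 0) for the 3 control libraries (grey) and the 3 exosome-treated libraries (red), with the mean and SD of each group in black beside the points. Serpine1, Thbs1, Fosl1 and Tagln were lower and Egr1, Sfrp2, Cfh and Dcn were higher in all 3 treated libraries than in any control.

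Across the transcriptome, changes were numerous and small. Of 12445 genes tested, 2106 were higher and 2192 were lower after exosome treatment by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The median size of the called changes was 0.25 on the log2 scale, or 1.19-fold. At least 2-fold changes were found in 93 of the higher and 17 of the lower genes, and 97.4% of the calls were smaller. In 6007 of the tested genes (48.3%) the 3 treated values did not overlap the 3 control values, against 10% by chance. The balance of directions depended on the scaling. With library totals in place of TMM factors, 3165 genes were higher and 1335 lower, 70.3% higher against 49% with TMM. Fold changes also followed transcript length, with a Spearman rho of -0.281 across 12145 genes, which are not independent replicates. With offsets for length and GC content, a setting added after the data were seen, 1798 genes were higher and 3094 lower (36.8% higher).

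The largest increases by the naming rule were in Cxcl15, Dhrs3, Fos, Egr1, Gda, C4b, Cfh and Plxdc1. Egr1, a growth factor-induced zinc finger factor, rose from 77.8 ± 4.17 to 235 ± 12.2 CPM (log2 fold change 1.59, adjusted p = 4.56e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fos, a subunit of the AP-1 transcription factor, rose 3.12-fold from a low level of 2.77 ± 0.323 CPM. The chemokine gene Cxcl15 rose 3.38-fold and the retinaldehyde reductase gene Dhrs3 3.2-fold, both from under 1.5 CPM. Complement factor H, encoded by Cfh, rose from 15.2 ± 0.728 to 36.5 ± 0.489 CPM. Sfrp2, a secreted modulator of Wnt signalling, rose from 77 ± 3.81 to 168 ± 11.9 CPM, and the alarmin cytokine gene Il33 from 29.1 ± 2.12 to 61.2 ± 3.17 CPM. Gda, encoding guanine deaminase, rose by 1.35 on the log2 scale and Plxdc1 by 1.20. Complement C4b rose by 1.33, but it shares reads with its near-identical copy C4a, so its level is uncertain.

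By the same rule, the largest decreases were in Lrp2, Prl2c2, Serpine1, Peg10, the growth factor gene Ngf, the AP-1 subunit gene Fosl1, Shank2 and Klf5. Lrp2, encoding the endocytic receptor megalin, had a log2 fold change of -1.46 at a low level (3.47 ± 0.274 CPM in controls), and the imprinted gene Peg10 had -1.05. Ngf, encoding nerve growth factor, fell from 21.7 ± 1.42 to 11 ± 0.103 CPM. Fosl1 fell from 50.7 ± 1.48 to 25.9 ± 1.68 CPM while Fos rose. Thrombospondin 1 (Thbs1), a matrix glycoprotein that activates latent TGF-beta, fell from 902 ± 10.4 to 510 ± 25.7 CPM (log2 fold change -0.82, adjusted p = 5.33e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The hyaluronan receptor gene Cd44 fell from 266 ± 1.26 to 168 ± 4.59 CPM, and the nucleolar helicase gene Ddx21 from 491 ± 4.65 to 328 ± 4.98 CPM. Shank2 and Klf5, a transcription factor of proliferating smooth muscle, had log2 fold changes of -0.89 and -0.88 from about 3 CPM. Prl2c2 had -1.21, but it belongs to a family of near-identical copies and its level is uncertain.

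Of 15 tested members of the contractile smooth muscle list, 7 fell, none rose and 8 did not pass the test (7 also fell when adjusted over the list alone). Tagln, encoding the actin-binding protein SM22-alpha, fell from 33.9 ± 0.741 to 18.5 ± 1.21 CPM. Acta2, encoding smooth muscle alpha-actin, fell from 784 ± 40.7 to 572 ± 37.5 CPM, and caldesmon (Cald1) from 899 ± 27.6 to 679 ± 8.43 CPM. Srf, the transcription factor that drives these genes, fell from 128 ± 4.06 to 91.8 ± 9.05 CPM. The smooth muscle myosin gene Myh11 was too low to test, with mean counts of 2.33 and 0.667 in the 2 groups. Control cells thus already held little of this contractile marker, and only 15 of the list's 20 members were high enough to test. The list had a median log2 fold change of -0.22 and an adjusted p of 0.0216 by camera with a preset correlation. That call was lost with an estimated correlation (adjusted p = 0.595 with an estimated correlation), with the replicate number as a block (adjusted p = 0.0536) and with length and GC offsets (adjusted p = 0.0661, 8 members lower). The median of the list was -0.22 with the block and -0.29 with the offsets.

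Genes of the synthetic, or modulated, smooth muscle state went both ways, with 9 of 18 tested members higher, 7 lower and 2 not past the test, both over all genes and adjusted over the list alone. Mgp, an inhibitor of calcification, rose by 0.75 on the log2 scale, the adhesion molecule gene Vcam1 by 0.36 and S100a4 by 0.35, whereas Thbs1 and Klf5 fell. The camera test of this list did not pass (adjusted p = 0.755), and length and GC offsets gave 6 higher and 7 lower members. In S phase and DNA replication, 2 of 25 members were higher and 4 lower, among them Pcna (0.17), the replication clamp, and Rrm2 (-0.25), a subunit of ribonucleotide reductase. In mitosis, 2 of 25 were higher and 4 lower (3 lower when adjusted over the list alone), with Ccnb2 at 0.27 and Foxm1, a driver of mitotic genes, at -0.19. The proliferation marker Mki67 had a log2 fold change of -0.14 that did not pass the test. Without exosome replicate 3, 8 members of each of these 2 lists were lower, and 1 to 2 were lower without exosome replicate 1 or any single control. Length and GC offsets gave 9 lower S phase and 11 lower mitosis members. With library totals 8 S phase members were higher and 1 lower and 3 mitosis members higher and 1 lower, and the median of the mitosis list moved from -0.05 to 0.01.

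Targets of the mechanosensitive YAP and TEAD factors were mostly lower, with 10 of 17 members lower, 3 higher and 4 not past the test, the same numbers as when adjusted over the list alone. Ankrd1 fell from 209 ± 7.46 to 159 ± 0.923 CPM, the receptor tyrosine kinase gene Axl had a log2 fold change of -0.29 and the Rho GTPase-activating gene Dlc1 had -0.60. Ccn2 (connective tissue growth factor) had -0.46, whereas its relative Ccn1 rose by 0.29 and the stress-response gene Gadd45a by 0.68. The list's median was -0.26 (camera adjusted p = 0.0216; adjusted p = 0.592 with an estimated correlation). An adjusted p of 0.255 was obtained with length and GC offsets, although 10 members were still lower.

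In cholesterol biosynthesis, 16 of 24 members rose, none fell and 8 did not pass the test, and 18 rose when adjusted over the list alone. Fdps, encoding farnesyl diphosphate synthase, rose from 180 ± 5.37 to 255 ± 13.3 CPM, and Insig1, a sterol sensor and feedback regulator, from 90.9 ± 5.1 to 121 ± 3.74 CPM. Msmo1 and Fdft1 rose by 0.30 and 0.33 on the log2 scale, while Ldlr, the LDL receptor gene, had 0.01 (adjusted p = 0.874, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median of the list was 0.22 (camera adjusted p = 7.52e-06; adjusted p = 0.592 with an estimated correlation). Among fatty acid synthesis and lipid storage genes 6 of 19 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.116). None fell with library totals, where 7 rose, and 1 fell without control replicate 2 or 3. The desaturase genes Scd1 and Scd2 and Fads1 each rose by 0.29, and Srebf1, encoding a master regulator of lipid synthesis, by 0.30. In lysosome and autophagy, 14 of 24 members rose and none fell (15 rose when adjusted over the list alone), including Map1lc3b (0.38), an autophagosome protein gene, the hexosaminidase gene Hexb (0.35) and the cathepsin gene Ctsd (0.23). That list's median was 0.16 (camera adjusted p = 0.000265; adjusted p = 0.595 with an estimated correlation). Its adjusted p was 0.104 with length and GC offsets, where 11 members were higher and 3 lower.

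Adventitial fibroblast markers were the list with the largest median increase among those past the camera test, 0.63 over 8 tested members, of which 5 rose, none fell and 3 did not pass the test (also 5 when adjusted over the list alone). The proteoglycan gene Dcn rose from 18.7 ± 0.866 to 37.2 ± 1.82 CPM and the growth factor receptor gene Pdgfra from 26.6 ± 0.865 to 36.6 ± 1.19 CPM. Ly6a and Ly6c1, surface antigen genes of stem-like and stromal cells, both rose by 0.78, at 8.13 ± 0.285 and 9.79 ± 0.578 CPM after treatment; the 2 are close paralogs that can share reads. The camera adjusted p was 0.000805 (adjusted p = 0.592 with an estimated correlation). Ly6a and Pdgfra also stand in the synthetic smooth muscle list and Dcn in the matrix list, and the fibroblast markers Lum, Pi16 and Clec3b were too low to test. Markers of other cell types were sparse. Of 4 tested endothelial markers Egfl7 and Eng rose, of 5 macrophage and leukocyte markers Lyz2 rose at under 1 CPM, neither of 2 adipocyte markers (Fabp4 and Pparg) passed, and of 4 epithelial and mesothelial markers Krt19 and Upk3b rose. The counts were the same when adjusted over the list alone. Of 6 pericyte markers, 4 rose, among them Notch3 (0.63), Anpep (0.45) and Rgs5 (0.35), and 2 fell, Cspg4 (-0.37) and Mcam (-0.16), likewise adjusted over the list alone, and 1 fell with library totals or without control replicate 1, control replicate 2, exosome replicate 1 or exosome replicate 2. None of these 5 lists passed the camera test. Egfl7, Eng, Lyz2, Krt19 and Upk3b each lost significance under at least 1 alternative setting.

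**Figure D2:**
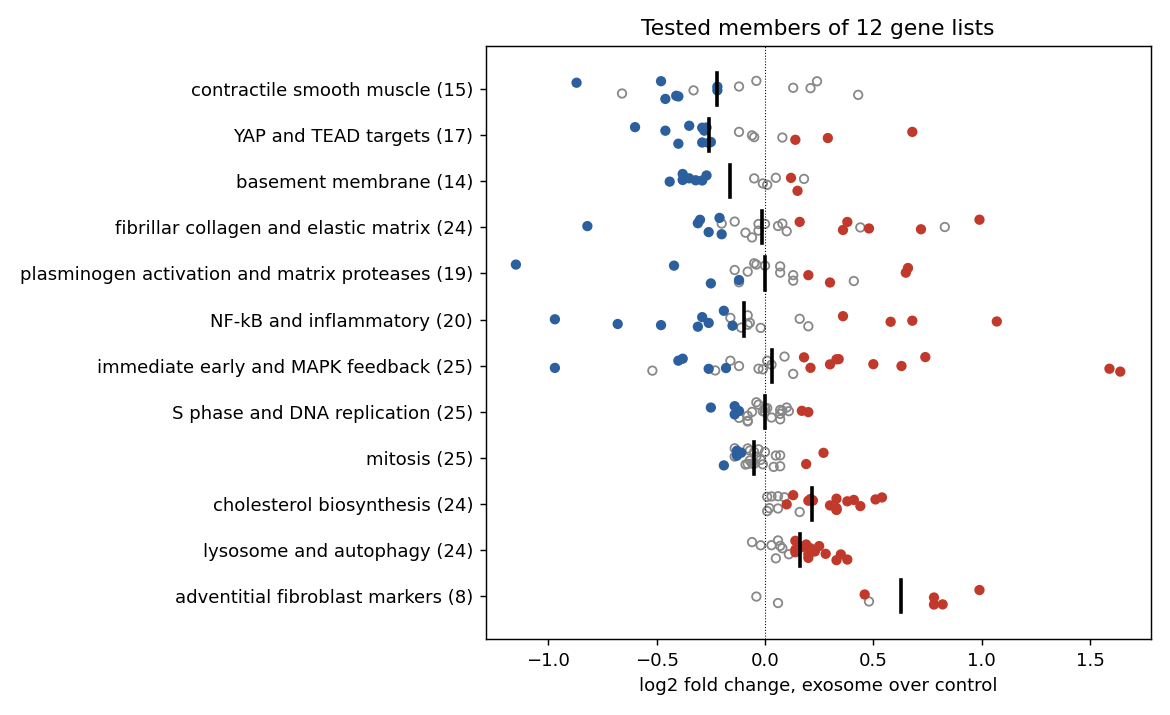
Each point is 1 tested gene of 12 of the 30 lists (rows, with the number tested in parentheses), placed by its log2 fold change, exosome over control (horizontal axis), with a small random vertical offset. Red points were higher and blue points lower at an adjusted p under 0.05, open grey points did not pass, and black bars mark list medians, which run from -0.26 for YAP and TEAD targets to 0.63 for adventitial fibroblast markers; with library totals the medians of the mitosis and the fibrillar collagen lists change sign.

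Extracellular matrix genes changed in both directions. In the fibrillar collagen and elastic matrix list 6 of 24 members rose and 6 fell, also when adjusted over the list alone. Col3a1 rose from 70 to 115 CPM and Col6a1 from 251 to 322 CPM, while Tnc (tenascin C) fell from 24.2 to 13.7 CPM. The main collagen genes Col1a1 (-0.09) and Col1a2 (0.00) did not pass the test. In the basement membrane list 7 of 14 members fell and 2 rose, also when adjusted over the list alone, and none rose without control replicate 1, control replicate 3 or exosome replicate 1. The laminin genes Lamb1 and Lamc1 had log2 fold changes of -0.44 and -0.29, nidogen 1 (Nid1) -0.38 and perlecan (Hspg2) -0.35. The camera test of the basement membrane list gave an adjusted p of 0.0716 (adjusted p = 0.595 with an estimated correlation). Over the other settings it lay between 0.0231 with limma-voom and 0.772 with length and GC offsets, where camera's direction turned to up. Within plasminogen activation and matrix proteases, 4 of 19 members fell and 4 rose (5 rose when adjusted over the list alone). The urokinase receptor gene Plaur had -0.42 and the protease inhibitor gene Timp3 -0.25, in the same direction as Serpine1, and the metalloproteinase gene Mmp19 rose by 0.66. Among TGF-beta response genes 6 of 20 rose and 8 fell (7 and 8 when adjusted over the list alone), against 8 and 5 with library totals. Only 5 fell without control replicate 1, control replicate 2 or exosome replicate 3. Pmepa1, a feedback inhibitor of the pathway, had -0.49, and the TGF-beta-induced matrix gene Tgfbi rose by 0.66. Neither list passed the camera test (adjusted p = 0.92 and 0.623).

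Signalling, inflammatory and stress lists changed member by member, and none passed the camera test. Among immediate early and MAPK feedback genes 10 of 25 rose and 5 fell, also when adjusted over the list alone. Ier2 rose by 0.74 beside Egr1 and Fos, and Fosl1 was the deepest decrease. Of 20 NF-kB and inflammatory genes 4 rose and 8 fell, also when adjusted over the list alone. Il33 rose, while Csf1, the macrophage growth factor gene, had -0.48 and Ptgs2, encoding cyclooxygenase 2, had -0.68. In the interferon response list 8 of 28 rose and 1 fell, also when adjusted over the list alone, led by the guanylate-binding protein genes Gbp2 (0.54), Gbp5 (0.83) and Gbp3 (0.37) and the immunity-related GTPase gene Iigp1 (0.57), members of multigene families whose single values are uncertain. Library totals gave 10 higher and none lower, length and GC offsets 9 and 3, and leaving out exosome replicate 3 gave 8 and 4. The median of the interferon list, 0.03, turned to -0.02 with length and GC offsets and to -0.03 without exosome replicate 3. Among p53 targets 4 of 21 rose and 5 fell (7 and 6 when adjusted over the list alone), against 8 and 5 with library totals and 2 and 9 with length and GC offsets, and 2 rose without control replicate 2, with Ddit4l at 1.06, Trp53inp1 at 0.62 and Aen at -0.55. In the unfolded protein and amino acid stress list 5 of 25 rose and 8 fell (7 and 10 when adjusted over the list alone). This balance was 7 and 4 with library totals, 4 and 13 with length and GC offsets and 6 and 12 without exosome replicate 3, and 4 to 5 members fell when any other library was left out. The stress-response genes Chac1 (0.53), Trib3 (0.45), Ddit3 (0.36) and Ddit4 (0.41) rose.

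Metabolic and growth factor lists were mixed. Of 23 hypoxia and glycolysis genes 5 rose and 3 fell, also when adjusted over the list alone, against 9 and 1 with library totals and 4 and 7 with length and GC offsets. These counts were 4 and 5 without exosome replicate 3, and 2 to 4 rose and 1 fell when any other library was left out. Hexokinase 2 (Hk2) was at -0.60 and Pdk1, which restrains pyruvate oxidation, at 0.35. Of 25 NRF2 and antioxidant genes 9 rose and 1 fell (10 and 1 when adjusted over the list alone). The glutathione transferase gene Gstm1 rose by 0.67, which is uncertain because it has close paralogs, Nqo1 rose by 0.35 and the ferritin heavy chain gene Fth1 by 0.32, while thioredoxin reductase 1 (Txnrd1) had -0.30. Under length and GC offsets 6 of the antioxidant genes were higher and 6 lower, and without exosome replicate 3 the numbers were 9 and 3. Camera passed for this list without exosome replicate 2 alone (adjusted p = 0.046). In oxidative phosphorylation 6 of 25 rose and none fell (2 rose when adjusted over the list alone), with a median of 0.07 that turned to -0.03 with length and GC offsets, where 1 member was higher and 5 lower and camera passed in the lower direction (adjusted p = 0.018). It passed in the higher direction with library totals (adjusted p = 0.0492) and without exosome replicate 2 (adjusted p = 0.046). Library totals gave 12 higher oxidative phosphorylation genes, and leaving out control replicate 1 or 2 gave 2. Of 28 cytosolic ribosomal protein genes 4 fell and none rose, also when adjusted over the list alone, with a median of -0.05 that was 0.01 with library totals. Of these genes 1 to 2 were lower when any other library was left out, 12 without exosome replicate 3 (camera adjusted p = 0.0049) and 27 with length and GC offsets (camera adjusted p = 1.73e-08), and camera also passed without a filter (adjusted p = 0.0494). Their many processed pseudogenes make single values uncertain. Of 7 osteogenic and chondrogenic genes 2 rose and 2 fell, also when adjusted over the list alone (1 fell without control replicate 1, control replicate 3 or exosome replicate 3, and 1 rose with length and GC offsets), with Bmp4 at 0.31 and Runx2, the master factor of bone formation, at -0.35. Of 20 growth factor receptors and ligands 6 rose and 6 fell, also when adjusted over the list alone, among them the receptor ligand gene Gas6 (0.48) and the hepatocyte growth factor receptor gene Met (-0.21). At the settings chosen in advance for all results, and not the alternatives, the camera test passed for none of these 6 lists and for 5 of the 30 lists in all, 0 of them with an estimated correlation, where 1 list had an unadjusted p under 0.05. The median, the mean and the camera direction did not share a sign for the fibrillar collagen, p53, unfolded protein, growth factor, plasminogen and adipocyte lists.

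The next question was whether messages with miR-148a-3p sites fell as a group. Among 31 tested genes published as miR-148a targets, 7 fell and 5 rose (9 and 5 when adjusted over the list alone). Serpine1 and Csf1 fell, whereas Gadd45a rose by 0.68 and Errfi1, a feedback inhibitor of the EGF receptor, by 0.43. The list had a median of -0.08 and an adjusted p of 0.249 by camera, whose direction turned to up with length and GC offsets (adjusted p = 0.57). The 3′ untranslated region (UTR) of Serpine1 is 1670 bases long in GENCODE M21 and lies on chromosome 5 from 137061504 to 137063173 on the minus strand of GRCm38. It holds 2 matches to bases 2 to 8 of the microRNA, TGCACTG, each followed by G. They start at UTR positions 1169 and 1497, at chromosome 5 from 137061999 to 137062005 and from 137061671 to 137061677 in GRCm38. Across all 12130 genes with a searched 3′ UTR, 2058 held such a site, of which 271 were higher and 479 lower, beside 2106 and 2192 over all tested genes. With library totals the genes with a site turned to 398 higher and 304 lower, beside 3165 and 1335 over all tested genes. The mean log2 fold change of genes with a site minus that of genes without one stayed at -0.049 there.

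Genes with a site had a lower mean log2 fold change than genes without one (difference -0.049, p = 0.0356 by camera with a preset correlation, and p = 0.245 with an estimated correlation). The 585 genes with 8mer sites alone had a difference of -0.054 (p = 0.0321 by camera with a preset correlation), and 26 of 100 shuffled seeds, not matched for their number of genes, lay at or below it. For all sites, of 100 shuffled seeds of the same base composition 20 lay at or below -0.049, but 17 of these 20 matched far fewer genes and scattered more. Among all 629 other orders of the seed's bases, 240 matched between 1038 and 2977 genes, 0.5 to 2 times the number of the miR-148a-3p seed, a choice made after the shuffled seeds were seen. Their median difference was -0.037, and 26 of the 240 (10.8%) lay at or below the miR-148a-3p seed. The difference of the miR-148a-3p seed was -0.011 under length and GC offsets, where 38 of 241 such orders (15.8%) lay at or below it, and -0.036 without exosome replicate 3. Camera did not pass in either and had its direction up with the offsets.

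**Figure D3:**
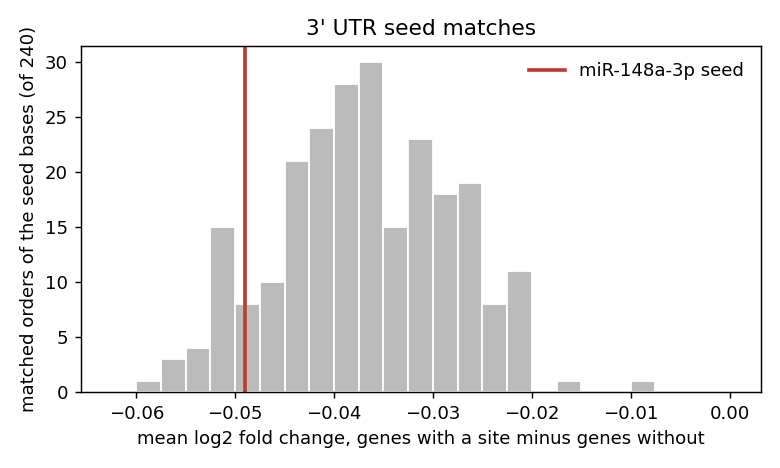
The grey histogram counts the 240 other orders of the seed's bases with a like number of genes (vertical axis) by the mean log2 fold change of genes with a 3′ UTR match minus that of genes without one (horizontal axis), and the red line marks the miR-148a-3p seed. The line at -0.049 lies inside their range, -0.058 to -0.0095.

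The libraries also differed in a length trend, beside the list and site results above. It differed between the groups and was strongest in exosome replicate 3, and its source was not tested. Tested genes were divided into 5 bins of transcript length. In the shortest bin (271 to 1646 bases), 693 were higher and 199 lower after treatment. In the longest bin (4775 to 26366 bases), 178 were higher and 736 lower. The longest minus the shortest bin was taken as the median log2 CPM deviation from the mean of all libraries. It came to 0.097, 0.11 and 0.054 in the 3 controls and -0.035, -0.0044 and -0.21 in exosome replicates 1, 2 and 3. Because that mean includes exosome replicate 3, the trend of that library also raised the values of the others. Exosome replicate 3 stood apart from the other treated libraries, with a chi-square per gene of 6.26 and 6.3 against them, where replicates 1 and 2 had 2.2 between them and pairs of controls 1.9 to 2.38. Without exosome replicate 3, 2135 genes were higher and 2456 lower, and 90.6% of the original calls were kept.

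**Figure D4:**
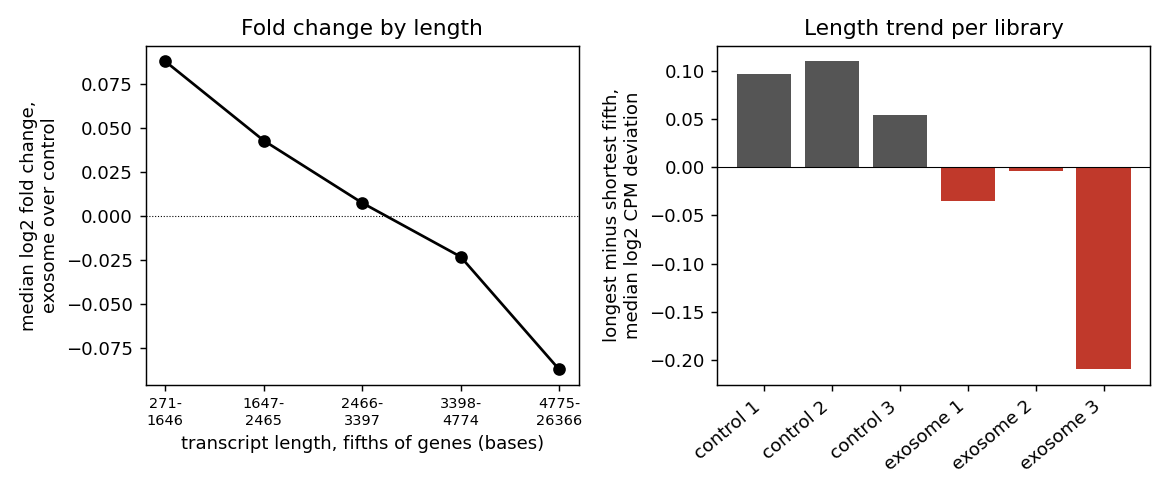
Left, the median log2 fold change, exosome over control (vertical axis), of the tested genes in 5 bins of transcript length in bases (horizontal axis) goes from 0.088 in the shortest to -0.087 in the longest. Right, bars give for each library the median log2 CPM deviation from the mean of all libraries in the longest minus the shortest bin. It is above 0 in the controls (grey). Treated libraries (red) run from -0.0044 in exosome replicate 2 to -0.21 in exosome replicate 3.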

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

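The length and GC offsets, the TPM tests and the seed-site test under settings other than 8mer sites and an estimated correlation were chosen after the results were seen. Serpine1 kept its direction and its side of the threshold under all 16 alternatives, with log2 fold changes from -1.18 to -1.09 and a largest adjusted p of 1.15e-07. No called gene was called in the opposite direction under any of the 16 alternative fits. The sign of genes that lost their call was not counted. Of 117 other named genes 115 were called, and 98 of these were never lost. With library totals 3165 genes were higher and 1335 lower, and 80.1% of the calls were kept. At a 2-fold minimum 93 were higher and 17 lower, and at an adjusted p under 0.01 the numbers of genes called higher and genes called lower were 1204 and 1347. The DESeq2 Wald test gave 1419 higher and 1827 lower genes. Leaving out each library gave 1578 to 2135 higher and 1558 to 2456 lower genes. Camera with an estimated correlation called 0 gene lists and fry called 14. The miR-148a-3p seed-site difference was -0.049 with an estimated correlation (p = 0.245), -0.011 with length and GC offsets (p = 0.217, camera's direction up), and -0.057 to -0.036 with each library left out, past the threshold except without control replicate 2 (p = 0.0512) or exosome replicate 3 (p = 0.109). Apart from fewer samples in the fits that leave out a library and stricter limits in the threshold settings, the cause was not tested. Same-numbered samples did not deviate together (correlations -0.042, 0.0026 and -0.018), so the numbers were not read as pairs. With the replicate block 2186 genes were higher and 2332 lower, and the contractile list had a camera adjusted p of 0.0536. Depth limits genes of a few counts, such as Lyz2 with mean counts of 4.33 and 13.3.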

Other observations

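The 4 gene lists in this and the next paragraph, their tests, and the tests of direct Serpine1 repression, seeds with a like number of genes, fibroblasts, cycling cells and length among contractile, YAP-target and fibroblast genes were chosen after the results were seen. Genes of nucleolar ribosome biogenesis, which make and assemble ribosomal subunits, were lower after exosome treatment. Of 50 tested, 48 fell and none rose at an adjusted p under 0.05, with a median log2 fold change of -0.35, and Imp3 and Polr1c did not pass. Nucleolin (Ncl) fell from 1980 to 1370 CPM, the RNA polymerase I subunit gene Polr1b had -0.52, Rrp12 had -0.64 and Heatr1 had -0.66. Camera gave p = 6.22e-25 for the list with a preset correlation and p = 0.00493 with an estimated correlation. The lower members numbered 49 with length and GC offsets, 47 with library totals and 48 without exosome replicate 3. Actin cytoskeleton genes regulated by SRF were also lower, with 18 of 23 members, among them Actb (-0.36), Vcl (-0.38), Actn1 (-0.42) and Fhl2 (-0.59), and 15 with library totals (camera p = 1.91e-08, and p = 0.0531 with an estimated correlation). Because these lists were drawn up from the changed genes, their p-values are not independent evidence.

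Complement genes were higher in 7 of 11 tested members, including Cfh, the protease genes C1s1 (0.85) and C1ra (0.55), C3 (0.33) and the uncertain C4b (camera p = 2.4e-05, and p = 0.0243 with an estimated correlation). Genes of xenobiotic and aldehyde metabolism were higher in 17 of 21, with Aldh3a1 at 0.97, Mgst1 at 0.88 and Gstt1 at 0.69 (camera p = 6.94e-10, and p = 0.0236 with an estimated correlation). Under length and GC offsets 14 of these 21 were higher. Gstp2 and Ugt1a6b share reads with near-identical copies and are uncertain.

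The first pattern weighed was the large number of small changes. With length and GC offsets 82.6% of the called genes were still called in the same direction, and without exosome replicate 3 the share was 90.6%, which argues against either as the whole cause. The real split called 4298 genes and the highest of the other splits called 0, so 1 of 10 splits gave as many, too few splits for a share under 0.05. Every other split also put treated and control libraries together, so the difference between the groups widened the spread and few calls could arise. Exosome treatment stays open as a hypothesis, and so does any difference in culture, such as cell density, vehicle or medium, that may have gone with the 2 groups and was not tested.

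For the fall of Serpine1, repression across messages with miR-148a-3p seed sites is a hypothesis that stays open. The limit written in advance against it was met, since 20 of 100 shuffled seeds lay at or below the real seed (difference -0.049, above their 5th percentile of -0.066), but that limit was wrong because 17 of these 20 seeds matched far fewer genes and so scattered more. Among orders with a like number of genes 10.8% lay at or below it, and it lay above their 5th percentile of -0.052. That percentile lies inside the 95% bootstrap interval of the difference over genes (-0.062 to -0.036). The limit against repression for these orders, set after the results were seen, asked for a percentile outside the interval and was not met. The orders already carry the scatter between genes, so that limit was hard to meet and decides neither way. With length and GC offsets the difference was -0.011, and 15.8% of such orders lay at or below it. The seed was not set apart from such orders in either setting, which does not exclude a small effect. A smooth length or GC bias is argued against by its size. Median log2 fold changes lay between -0.087 and 0.088 over the bins of length and between -0.027 and 0.061 over those of GC content. The log2 fold change of -1.18 with offsets adds little, because offsets for trends of that size could not have removed the fall. Direct repression of Serpine1 through its own 2 seed matches may still account for the fall. It cannot be told apart from other effects of the exosomes, because the 6 libraries hold no arm given exosomes that lack the microRNA.

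The third pattern was lower contractile and YAP-target genes with higher fibroblast markers. A larger share of adventitial fibroblasts stays open. The markers Lum, Pi16, Cd34, Dpep1, Clec3b and Mfap5 had a highest mean of 0.37 CPM in treated libraries. They are the members of the list too low to test and were picked after the results were seen, so their low level cannot decide. Of the 8 tested members 5 rose and none fell. The fall of Tagln alone would need fibroblasts to make up 45.4% of the cells. That share assumes no fibroblasts in controls, no Tagln in fibroblasts and equal RNA per cell. Other members such as Acta2 (0.729 of its control level) fell less than Tagln (0.546). Fibroblasts that lose these transcripts in culture were not tested. Fewer cycling cells as the whole cause are argued against by a median of -0.035 over 50 S phase and mitosis genes. The bound of -0.2 was set after the results were seen. With single libraries left out the median ran from -0.065 without exosome replicate 3 to -0.015 without exosome replicate 1. The 95% bootstrap interval of -0.069 to 0.0016 resampled genes with estimated correlations of 0.403 (S phase) and 0.197 (mitosis). It holds no spread between libraries. A smaller change in cycling cells stays open in either direction. The median was -0.043 (-0.086 to -0.015, also over genes) under length and GC offsets and 0.022 (-0.012 to 0.059) with library totals. With length and GC offsets the 22 members that make up the pattern (7 contractile and 10 YAP-target genes that fell and 5 fibroblast markers that rose) were still called in the same direction, although the camera calls of the contractile and YAP lists were lost. Another candidate explanation left open is a shift of the smooth muscle cells themselves, from the exosomes or from culture density. It remains a hypothesis found on these data and was not itself tested.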
